A study of Arabidopsis thaliana with 12 samples.

How the data were processed

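RNA sequencing libraries were compared from seedlings of the Arabidopsis thaliana accession Col-0 and of the line bbx28-5, kept in white light or moved to simulated shade, with 3 biological replicates and 3 libraries in each of the 4 groups. Per the labels, the seedlings grew for 2 days in short days of 10 h light and 14 h dark on agar and water and were then exposed for 4 h. White light had a photosynthetically active radiation of 90 and simulated shade, under a green filter, of 20 µmol per square metre per second. The red to far-red ratio was 1.1 in white light and 0.145 in shade, and blue light was lower in shade as well, at 1.3 against 8.1. Libraries were made with a stranded mRNA kit, and the strand setting used in counting is not given in the sources used here. The kind of lesion in bbx28-5 is not given either.

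The authors deposited a table of raw counts of reads per gene and a filtered, normalized table. Per the submitters' processing notes, reads were handled with FastQC, HISAT, SAMtools, HTSeq and edgeR on the TAIR10 build, with no versions given. In the deposited raw table the unit is counts, whole numbers for 32833 genes in 12 libraries. In the deposited normalized table the unit is log2, the log2 of counts per M (mega) of the library size (CPM) after scaling by the trimmed mean of M values (TMM), with an offset of 0.5, for 19724 genes by a filter that is not stated. Recomputing it from the raw counts gave differences of at most 5e-14. The normalized table served as a check and as an alternative choice of genes, and all tests started from the counts. Gene symbols came from a TAIR10.1 annotation, in which 32548 of the 32833 identifiers were found. No coordinates were taken from it for the text.

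Total counts per library ran from 10.61 to 14.3 M. At these totals a floor of 3 counts corresponded to 0.21 to 0.283 CPM, and intervals and floors cover counting error only. Genes were kept with filterByExpr of edgeR, which left 19711 genes holding 99.93% of the counts. One quasi-likelihood model was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3, with TMM scaling and a mean per group, and p values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were shade against white light in each genotype, bbx28-5 against Col-0 in each light, and the interaction, which is the shade effect in bbx28-5 minus that in Col-0. Fold changes are log2 values with a standard error (SE) derived from the test statistic. That SE rests on a spread shared by all 4 groups, so it does not show the spread within a group. CPM values carry the standard deviation (SD) of 3 libraries.

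Before the data were examined, 22 gene lists with 300 members were fixed, of which 284 were tested: shade markers, auxin response, auxin biosynthesis and transport, light signalling, the BBX family, cell wall expansion, brassinosteroid, gibberellin, flavonoid and anthocyanin, light harvesting and photosynthesis, photoprotection, chlorophyll biosynthesis, circadian clock, sugar starvation, jasmonate and defence, cytokinin response, abscisic acid with cold or drought, heat shock, touch and wound, root markers, seed storage and maturation, and reference genes. The 300 members are different genes, and some lists share members. XTH15 is in the shade marker and cell wall lists and XTH22 in the cell wall and touch and wound lists. IAA19 and IAA29 are in the shade marker and auxin response lists. Results of lists that share members are therefore not fully separate. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 22 lists. The same test with an estimated correlation and the self-contained test fry were run beside it. Numbers of changed members are given from the adjustment over all genes and, where stated, adjusted over the list alone.

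Named genes were chosen by a rule fixed in advance. In each contrast these were BBX28, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups (a condition not used for the interaction), and up to 4 members of each list with the smallest adjusted p. About 20 to 30 of these are named per comparison, with preference for genes whose call did not depend on 1 library or on the scaling. Fold changes against a group with 1 to 3 counts in all are given as ratios with exact binomial 95% intervals.

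A shade response score was computed per library as the mean of log2 CPM (prior count 2) over genes called for the shade effect averaged over both genotypes, each multiplied by the sign of that effect. The difference in score response between the genotypes was tested with a two-sided exact permutation test over 400 arrangements of the genotype labels within each light. Replicate numbers did not pair libraries across groups. Correlations of residuals between libraries of the same number ran from -0.258 to 0.197 over 12714 genes, 3 of 18 were above 0.1 and 4 of 18 were highest with their own number, so no replicate term was used.

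Alternatives were scaling by relative log expression (RLE) or by total counts, other low-count filters, DESeq2 1.42.0, limma-voom, stricter thresholds, a replicate term, each library left out in turn, only the 6 libraries of a comparison, and offsets per library from 20 bins of GC content or transcript length. The pipeline was tested on simulated data in which 200 of 19711 genes were changed, 100 of them 2-fold and 100 of them 1.5-fold. For a comparison of 3 with 3 libraries edgeR recovered 70 of the 2-fold and 32 of the 1.5-fold changes with 8 false calls, and for the interaction 40 and 0 with 3 false calls. For the interaction DESeq2 recovered 55 and 9, with 10 false calls. No shade effect was simulated for these counts, so far fewer genes changed than in the real data. Sequence variants and splice forms were not analysed here.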

Results

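RNA was measured in seedlings to ask how BBX28, a B-box zinc finger protein, affects the transcriptional response to shade. The 12 libraries formed 4 groups of 3, Col-0 and bbx28-5 in white light and in 4 h of simulated shade. Mean total counts were 13.31 ± 1.12 M in Col-0 in white light, 13.34 ± 0.95 M in Col-0 in shade, 12.37 ± 1.39 M in bbx28-5 in white light and 11.36 ± 1.01 M in bbx28-5 in shade (SD, n = 3). The main axis of a multidimensional scaling held 65.5% of the variation and separated the lights, and the next axis held 14.6% and separated the genotypes. Replicates were alike in 3 groups, with correlations of log2 CPM across genes of at least 0.987. Col0_WL replicate 3 still stood apart for 2 gene lists. Its mean log2 CPM was 4.916 for the abscisic acid list, against 3.231 and 3.196 in Col0_WL replicates 1 and 2. For the flavonoid list it was 3.15, against 2.265 and 2.033. In the bbx28-5 shade group replicate 2 stood apart, with correlations of 0.964 with the other libraries of its group and 2151 genes at least 2-fold from their mean, against 129 to 742 in the other 11 libraries. The TMM factors of the bbx28-5 shade group averaged 0.841 ± 0.0442, against 1.04 ± 0.0218 in Col-0 in shade (SD, n = 3). Scaling by total counts instead lowered log2 values by about 0.34 for shade in bbx28-5, 0.31 for genotype in shade and 0.29 for the interaction. For shade in Col-0 and genotype in white light the amounts were about 0.05 and 0.013. These are differences of mean log2 scaling factors, and list medians moved by similar but not identical amounts. Directions are therefore given relative to TMM.

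The question of the Col-0 comparison was which transcripts respond to 4 h of shade in the wild type. All 14 shade markers rose. HFR1, a bHLH protein that restrains phytochrome-interacting factors, went from 20.8 ± 1.79 to 136 ± 4.26 CPM (SD, n = 3), a log2 change of 2.71 ± 0.0997 (SE, adjusted p = 7.77e-11). XTH15, a xyloglucan-modifying enzyme, rose by 7.05 ± 0.237 on the log2 scale from 24.7 ± 8.43 to 3260 ± 215 CPM. The homeodomain factor ATHB2 rose by 3.07 ± 0.132. In the same seedlings the dark-inducible gene SEN1 (AT4G35770) rose by 7.50 ± 0.302 and the asparagine synthetase gene ASN1 by 5.38 ± 0.216, while PORC, an enzyme of chlorophyll synthesis, fell by 2.74 ± 0.126.

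In total 11716 of 19711 genes changed in Col-0, 5726 higher and 5990 lower in shade, and 4731 of them at least 2-fold. Among the largest rises were BCAT-2, a branched-chain aminotransferase gene (6.45 ± 0.123 log2, from 10.8 ± 0.812 to 941 ± 3.86 CPM), the threonine aldolase gene THA1 (6.40 ± 0.261) and the small polypeptide gene RTFL21 (5.70 ± 0.14). The largest falls included IMD1, an isopropylmalate dehydrogenase gene, which went from 41.9 ± 11 to 0.245 ± 0.164 CPM (-7.39 ± 0.36), and the root growth factor peptide gene RGF9, which went from 73.1 ± 8.39 to 1.87 ± 0.519 CPM.

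Growth and light signalling lists differed in how uniformly they moved. The shade marker list passed (adjusted p = 1.74e-13) and kept its call with an estimated correlation (adjusted p = 0.00962), with 14 of 14 higher also when adjusted over the list alone. Of 20 auxin response genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 1.59e-06), with IAA19 at 2.13 ± 0.0926, IAA2 at 2.40 and GH3.5 at 2.07. With an estimated correlation the adjusted p of this list was 0.0782. Of 10 genes for auxin biosynthesis and transport 2 rose and 3 fell (adjusted p = 0.64). YUC8, a flavin monooxygenase gene of auxin synthesis, rose by 1.54 ± 0.155, whereas TAA1, which acts one step earlier, fell by 1.35. Of 15 cell wall expansion genes 10 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.000102, and adjusted p = 0.0294 with an estimated correlation), XTH24 by 3.61 and XTH22 by 3.74. Light signalling genes went both ways, 7 higher and 7 lower of 20 (adjusted p = 0.95), with a median of 0.06 and a mean of -0.06. The photoreceptor gene PHYA rose by 3.05 ± 0.119 and PIF7, a bHLH factor of the shade response, fell by 2.21 ± 0.107. Of 27 tested BBX genes 12 rose and 11 fell (13 and 11 adjusted over the list alone; adjusted p = 0.65), with BBX17 at 4.02 ± 0.158 and BBX3 at -1.62.

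Pigment and photosynthesis lists were lower in shade. Of 12 tested flavonoid and anthocyanin genes 10 fell and 1 rose, the same adjusted over the list alone (median -3.16, and -3.02 with 2 members of few counts at their bound; adjusted p = 0.00149), including FLS1, flavonol synthase, at -3.88 ± 0.169 and CHS, chalcone synthase, at -1.67 ± 0.138. The adjusted p of that list was 0.272 with an estimated correlation. Of 13 chlorophyll biosynthesis genes 10 fell and none rose (adjusted p = 7.16e-08, and adjusted p = 0.00962 with an estimated correlation), among them HEMA1, which commits glutamate to tetrapyrroles, at -1.84. Of 23 light-harvesting and photosynthesis genes 13 fell (adjusted p = 0.00155), with adjusted p = 0.589 with an estimated correlation. The Rubisco small subunit gene RBCS1B went from 644 ± 47.8 to 78 ± 16.4 CPM and the Rubisco activase gene RCA from 12200 ± 444 to 4500 ± 325 CPM (SD, n = 3). All 7 photoprotection genes fell (adjusted p = 0.000874; adjusted p = 0.051 with an estimated correlation), with ELIP2 at -2.60 and PSBS, a photosystem II protein of energy dissipation, at -1.57 ± 0.126.

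All 9 sugar starvation genes rose (median 3.04; adjusted p = 5.68e-19, and adjusted p = 0.00962 with an estimated correlation), DIN4 by 3.68 ± 0.101 and DIN10 by 3.54. Of 22 clock genes 15 rose and 2 fell (adjusted p = 2.11e-05, and adjusted p = 0.04 with an estimated correlation), with RVE7 at 3.48 ± 0.119 and TOC1 at 1.67. Of 11 tested jasmonate and defence genes 9 fell and 1 rose (adjusted p = 0.000645; adjusted p = 0.0782 with an estimated correlation), led by the lipoxygenase gene LOX2, from 97 ± 17.7 to 3.17 ± 0.422 CPM. Of 6 heat shock genes 5 rose (adjusted p = 0.00289; adjusted p = 0.188 with an estimated correlation) and of 6 touch and wound genes 5 rose (adjusted p = 0.000972, and adjusted p = 0.0294 with an estimated correlation), with HSP90.1 at 3.31 and the calmodulin-like gene TCH3 at 1.98. For these 5 lists the counts were the same adjusted over the list alone. Of 11 brassinosteroid genes 4 rose and 2 fell (adjusted p = 0.0401), with adjusted p = 0.147 with an estimated correlation. That call ended under total counts (adjusted p = 0.0548), with a replicate term (0.058) and without any 1 of Col0_WL replicates 1 to 3 (0.0547, 0.052 and 0.0577) or bbx28_SS replicate 2 or 3 (0.0756 and 0.0525).

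The other lists did not pass in Col-0. Gibberellin genes had 9 higher and 4 lower of 17 (adjusted p = 0.0877), cytokinin response genes 6 lower of 8 (0.181), abscisic acid genes 2 higher and 1 lower of 7 (0.781), root markers 2 higher and 4 lower of 14 (0.781), seed genes 1 higher and 1 lower of 12 (0.934) and reference genes 2 higher of 4 (0.417). The cytokinin response regulator ARR7 fell by 2.60 and the growth repressor gene GAI rose by 1.11. IRT1, an iron transporter of roots, was 45.9-fold lower by counts (3 against 142, 95% interval 15.4 to 225). Abscisic acid genes had a median of 0.37 and a mean of -0.68, and their level in Col0_WL replicate 3 stood apart, as given above. Adjusted over the list alone gibberellin genes had 10 higher and 4 lower, and every other list in Col-0 whose count is given once had the same count.

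**Figure D1:**
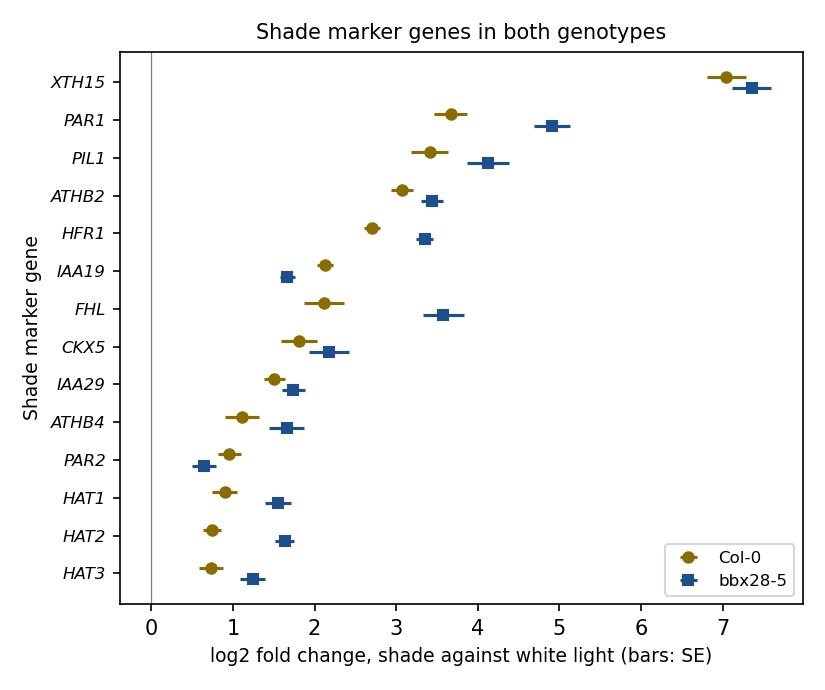
Log2 fold change of shade against white light (x axis) for the 14 shade marker genes (y axis) in Col-0 (circles) and bbx28-5 (squares). SE bars come from the joint fit of all 12 libraries, 3 per group. All 14 lie above 0 in both genotypes, XTH15 highest at 7.05 and 7.36; with total counts all stay above 0 as well, with 14 and 13 past the threshold.

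The same comparison in bbx28-5 asked whether the line still responds to shade. All 14 shade markers rose there too, HFR1 by 3.35 ± 0.102 (adjusted p = 9.19e-12), XTH15 by 7.36 ± 0.242, ATHB2 by 3.44 ± 0.135 and PAR1, an atypical bHLH protein, by 4.91 ± 0.216 (log2, SE, n = 3 per group). ASN1 rose by 5.73 ± 0.219 and SEN1 (AT4G35770) by 6.77 ± 0.291. The calmodulin-like gene TCH3 rose from 14.2 ± 1.16 to 212 ± 12.9 CPM (3.90 ± 0.117). RBCS1B fell from 839 ± 55.3 to 80 ± 21.6 CPM. MYB28, a regulator of aliphatic glucosinolate synthesis, fell from 36 ± 0.718 to 0.732 ± 0.322 CPM.

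In bbx28-5 13308 genes changed with shade, 6786 higher and 6522 lower, and 6879 at least 2-fold. Scaling by total counts gave 13687, 4644 higher and 9043 lower, or 33.9% higher against 51%. Of the genes called in both genotypes 10145 had the same direction, 5111 higher (1970 by chance) and 5034 lower (1980 by chance), and 55 the opposite (3960 by chance). The log2 changes correlated at r = 0.892 across genes, which are not independent replicates. The largest rises included RTFL21 (8.31 ± 0.184), and the small heat shock protein genes HSP23.6-MITO (7.10), ATHSP22.0 (6.78), HSP17.4 (6.68 ± 0.366) and HSP17.6A (6.55). The largest falls included AT2G27420, annotated as a cysteine proteinase (-7.78), RGF9 (-5.47) and IMD1 (-5.38).

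Of 20 auxin response genes 16 rose and 1 fell, the same adjusted over the list alone (adjusted p = 7.49e-06; adjusted p = 0.0939 with an estimated correlation), GH3.5 by 2.84 and IAA2 by 3.03. Of 15 cell wall genes 8 rose and 4 fell (adjusted p = 0.0234; adjusted p = 0.144 with an estimated correlation), with XTH22 at 4.70 and the expansin gene EXPA5 at -3.23. With total counts 7 rose and 6 fell, with a median of 0.12 against 0.45. Of 11 brassinosteroid genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.022; adjusted p = 0.0939 with an estimated correlation), CPD, a biosynthesis gene, by 2.79. The median of that list was 0.29 and turned to -0.04 with total counts, and 4 of its genes fell with total counts or without bbx28_SS replicate 2. Shade markers passed at adjusted p = 3.47e-12 (adjusted p = 0.00832 with an estimated correlation), sugar starvation genes with 9 of 9 higher at 3.1e-15 (adjusted p = 0.00832 with an estimated correlation) and touch and wound genes with 5 of 6 higher (6 adjusted over the list alone) at 7.92e-06 (adjusted p = 0.00832 with an estimated correlation). Heat shock genes rose in 6 of 6 (median 4.39; adjusted p = 0.000359; adjusted p = 0.163 with an estimated correlation), with HSP90.1 at 4.88 and HSP101 at 3.23. Clock genes had 15 higher and 2 lower of 22 (adjusted p = 2.53e-05; adjusted p = 0.0578 with an estimated correlation), with LUX at 2.46 and TOC1 at 2.29.

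Of 13 chlorophyll biosynthesis genes 9 fell and 2 rose (adjusted p = 0.000237; adjusted p = 0.0578 with an estimated correlation), with PORC at -2.04 and CHLI1 at -2.04, and with total counts none rose. Of 12 flavonoid genes 10 fell and 1 rose (median -3.01, and -2.02 with 4 members of few counts at their bound; adjusted p = 0.026; adjusted p = 0.445 with an estimated correlation), FLS1 by 3.58 log2 units. That call ended without bbx28_SS replicate 2 (adjusted p = 0.101) or 3 (0.0521) and with total counts (0.0628). Of 7 photoprotection genes 4 fell (adjusted p = 0.0297; adjusted p = 0.166 with an estimated correlation), PSBS by 0.71 and ELIP2 by 2.58, and with total counts all 7 did. Of 11 jasmonate and defence genes 7 fell and 2 rose (adjusted p = 0.0283; adjusted p = 0.245 with an estimated correlation), AOC1 at -4.33 and the repressor gene JAZ7 at 3.95. Without bbx28_SS replicate 3 the photoprotection and jasmonate calls ended (adjusted p = 0.0521 for both), and without replicate 2 the photoprotection median went from -0.49 to -0.85. Light-harvesting genes had 7 higher and 10 lower of 23 (adjusted p = 0.369), and without bbx28_SS replicate 2 they had 7 and 13 and passed as lower (adjusted p = 0.0302), as did cytokinin response genes (adjusted p = 0.0356), of which 7 of 8 fell and 1 rose with all libraries (0.099). With total counts light-harvesting genes had 3 higher and 13 lower, with a median of -0.52 against -0.16. The counts in this paragraph were the same adjusted over the list alone.

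Lists that did not pass in bbx28-5 were auxin biosynthesis and transport (1 higher, 6 lower of 10, adjusted p = 0.271), light signalling (7 and 8 of 20, 0.727), gibberellin (10 and 4 of 17, 0.14), abscisic acid (4 and 0 of 7, 0.554), root markers (4 and 6 of 14, 0.785), seed genes (3 and 0 of 12, 0.554) and reference genes (4 and 0 of 4, 0.121). Adjusted over the list alone seed genes had 1 higher, and the other lists in bbx28-5 whose count is given once had the same count. Without bbx28_SS replicate 2 seed genes had 7 higher and without replicate 1 they had 1. With total counts the numbers higher and lower were 5 and 11 for light signalling, 8 and 5 for gibberellin, 2 and 1 for abscisic acid and 1 and 0 for seed genes. BBX genes had 13 higher and 12 lower of 27 (14 and 12 adjusted over the list alone; adjusted p = 0.793), and their median of 0.21 turned to -0.12 with total counts. PHYA rose by 3.03, PIF4 by 1.00 and BBX27 by 2.64, and YUC2 fell by 1.25.

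The genotype comparison in white light asked what differs before any shade is given. CSD2, a copper/zinc superoxide dismutase of the chloroplast, was 445 ± 39.8 CPM in bbx28-5 against 42 ± 5.77 in Col-0 (SD, n = 3), higher by 3.41 ± 0.148 log2 units (SE, adjusted p = 1.84e-08), and CCS (AT1G12520), its copper chaperone, was higher by 2.35 ± 0.149. FRO5, a ferric reductase family gene, went from 34.1 ± 15.3 to 1.57 ± 1.01 CPM (-4.38 ± 0.439) and the copper transporter gene COPT2 fell by 2.64 ± 0.244. CYP86A1, a fatty acid hydroxylase of suberin synthesis, went from 53.8 ± 2.87 to 8.25 ± 0.786 CPM (-2.70 ± 0.167, adjusted p = 4.74e-07). The seed storage albumin gene SESA3 was higher by 6.91 ± 0.885 (0.335 against 43.2 ± 21.2 CPM). The early light-induced genes ELIP2 and ELIP1 were higher by 1.89 ± 0.171 and 1.51 ± 0.195.

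BBX28 itself (AT4G27310, chromosome 4) was detected in all 12 libraries. It measured 70.3 ± 5.41 CPM in Col-0 and 104 ± 4.14 CPM in bbx28-5 in white light, and 109 ± 5.34 and 171 ± 34.2 CPM in shade (SD, n = 3). Its log2 change was 0.57 ± 0.124 by genotype in white light (SE, adjusted p = 0.0101) and 0.65 ± 0.123 in shade (0.00122). Shade raised it by 0.63 ± 0.124 in Col-0 (adjusted p = 0.000517) and 0.72 ± 0.124 in bbx28-5 (0.000135), and the interaction was 0.08 ± 0.174 (0.798). Scaling by total counts lowers log2 values by about 0.31 for genotype in shade, 0.34 for shade in bbx28-5 and 0.29 for the interaction. These amounts are large beside 0.65, 0.72 and 0.08. Without Col0_WL replicate 3 the white light difference was 0.50 (adjusted p = 0.0517). Without a stated lesion the transcript level does not test the genotype label.

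**Figure D2:**
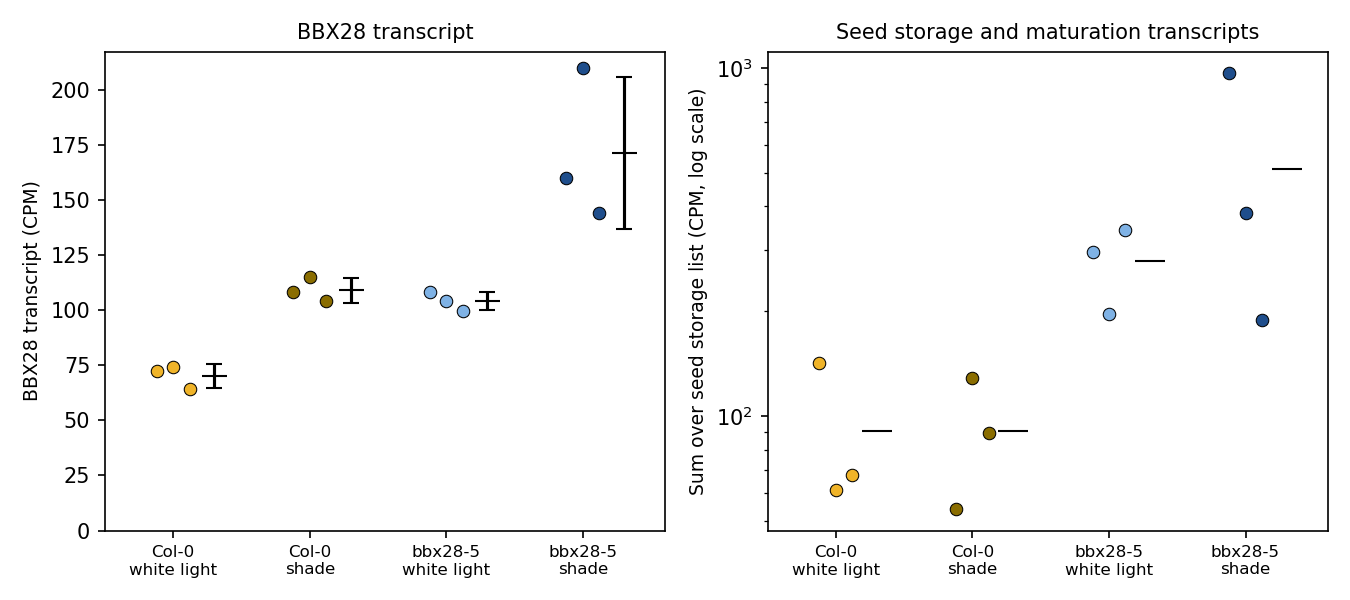
BBX28 transcript (left, CPM, mean and SD beside the points) and the summed seed storage and maturation list (right, CPM on a log axis, mean beside the points) in each of the 12 libraries by group. BBX28 averages 70.3, 109, 104 and 171 CPM from left to right, and all 6 bbx28-5 libraries have a seed sum above the highest Col-0 library, 141.7 CPM.

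In white light 1947 genes differed by genotype, 749 higher and 1198 lower in bbx28-5, and 545 at least 2-fold (104 higher, 441 lower). With offsets for transcript length, chosen after the data were seen, 1419 were higher and 1357 lower. The number depended on single libraries: it was 1054 without Col0_WL replicate 1, 1075 without Col0_WL replicate 2, 1231, 1001 and 994 without bbx28_WL replicates 1, 2 and 3, and 4766 without bbx28_SS replicate 2, a library of neither group compared. In a fit of only the 6 libraries compared it was larger as well, and above the number that such a fit gave in shade. Other falls among the largest were AT5G37690, annotated as an SGNH hydrolase-type esterase (-3.01 ± 0.152), and AT2G23540 (-2.59 ± 0.105), and other rises were MIOX4, a myo-inositol oxygenase gene (3.29), the defensin-like gene LCR67 (3.33 ± 0.533) and the vicilin-like seed storage gene PAP85 (2.52).

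Of 12 seed storage and maturation genes 7 were higher and none lower (10 adjusted over the list alone; median 2.95, and 2.62 with 1 member of few counts at its bound; adjusted p = 5.3e-09; adjusted p = 0.186 with an estimated correlation). The summed seed list was 278 ± 74.9 CPM in bbx28-5 and 90.2 ± 44.7 CPM in Col-0. Photoprotection genes passed with 2 of 7 higher (3 adjusted over the list alone; adjusted p = 2.5e-06, and adjusted p = 0.0412 with an estimated correlation). Clock genes had 4 of 22 higher (8 adjusted over the list alone; adjusted p = 0.00179; adjusted p = 0.191 with an estimated correlation), the morning genes LHY by 0.93 ± 0.118 and CCA1 by 0.49 ± 0.099. Sugar starvation genes had 3 of 9 higher (5 adjusted over the list alone; adjusted p = 0.00179; adjusted p = 0.248 with an estimated correlation), TPS11 by 0.74 ± 0.155. Light signalling genes had 3 of 20 higher, also over the list alone (adjusted p = 0.0206; adjusted p = 0.635 with an estimated correlation).

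Jasmonate and defence genes were lower in 5 of 11 and higher in none (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.000141; adjusted p = 0.159 with an estimated correlation), with the vegetative storage genes VSP1 at -1.77 ± 0.205 and VSP2 at -1.18, and the repressor gene JAZ1 at -0.80. Root markers were lower in 5 of 14 (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00819; adjusted p = 0.213 with an estimated correlation), the Casparian strip genes CASP1 by 0.95 ± 0.12 and CASP2 by 0.77 log2 units. Cell wall genes were lower in 3 of 15 (adjusted p = 0.0356; adjusted p = 0.243 with an estimated correlation), XTH17 at -1.03 ± 0.136 and XTH9 at -0.90 ± 0.125. Shade markers were lower in 3 of 14 (adjusted p = 0.0443; adjusted p = 0.395 with an estimated correlation), PAR1 at -1.03 ± 0.222. The cell wall call ended without Col0_WL replicate 2 (adjusted p = 0.101) or bbx28_WL replicate 3 (0.0553), and the shade marker call without Col0_WL replicate 2 (0.0851) or bbx28_WL replicate 2 (0.0776) or 3 (0.0637).

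The other 13 lists did not pass in white light. They were auxin response (3 lower of 20, adjusted p = 0.0909), auxin biosynthesis and transport (3 lower of 10, 0.178), BBX (3 higher and 1 lower of 27, 0.178), brassinosteroid (1 lower of 11, 0.478), gibberellin (2 lower of 17, 0.575), flavonoid (none of 12, 0.575), light harvesting (1 lower of 23, 0.393), chlorophyll (2 higher and 1 lower of 13, 0.747), cytokinin (none of 8, 0.809), abscisic acid (none of 7, 0.575), heat shock (1 higher of 6, 0.399), touch and wound (1 lower of 6, 0.575) and reference genes (none of 4, 0.478). Adjusted over the list alone the counts differed for auxin biosynthesis and transport (1 higher and 3 lower), gibberellin (1 and 2), light harvesting (none), abscisic acid (1 lower) and touch and wound genes (1 and 1), and for no other list of this paragraph, nor for cell wall genes or shade markers. Medians and means differed in sign for gibberellin (0.03 and -0.08), flavonoid (0.02 and -0.18) and cytokinin genes (0.03 and -0.10), and the test pointed down, up and down. Without 1 library some of these passed: auxin response as lower without bbx28_WL replicate 1 (0.0245) or bbx28_SS replicate 2 (0.0441), light harvesting as lower without bbx28_SS replicate 2 (0.0271), and flavonoid genes as higher without Col0_WL replicate 3 (0.0288). With total counts 3 light-harvesting genes were lower. PORB, a protochlorophyllide oxidoreductase gene, went from 299 ± 24.5 to 127 ± 3.17 CPM (-1.24 ± 0.0875, adjusted p = 1.43e-06). By locus number PORB (AT4G27440) lies close to BBX28. BBX32 was higher by 1.01 ± 0.195, YUC5 lower (-1.34) and the brassinosteroid oxidase gene BR6OX1 lower (-1.01 ± 0.202).

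The genotype comparison in shade asked how the seedlings differ once shaded. HFR1 was higher in bbx28-5, 234 ± 15.2 against 136 ± 4.26 CPM (SD, n = 3; log2 0.78 ± 0.0916, SE, adjusted p = 3.12e-05), and so was the homeodomain gene HAT2 (0.87 ± 0.112, adjusted p = 6.92e-05). Lower in bbx28-5 were the cell wall genes EXPA5, 2.48 ± 0.3 against 10 ± 0.446 CPM (-2.02 ± 0.143, adjusted p = 6.64e-07), XTH17 (by 2.08 ± 0.151) and XTH19 (by 1.56 ± 0.18). RCA was higher, at 8870 ± 824 against 4500 ± 325 CPM and so was PSBS, at 1400 ± 310 against 662 ± 21.8 CPM. HSP17.4 was higher by 2.80 ± 0.266 and TCH3 by 1.19 ± 0.102. CHS was 59 ± 2.81 against 23.8 ± 1.65 CPM and the clock gene CCA1 250 ± 30.5 against 100 ± 2.91 CPM. None of these directions turned with total counts.

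**Figure D3:**
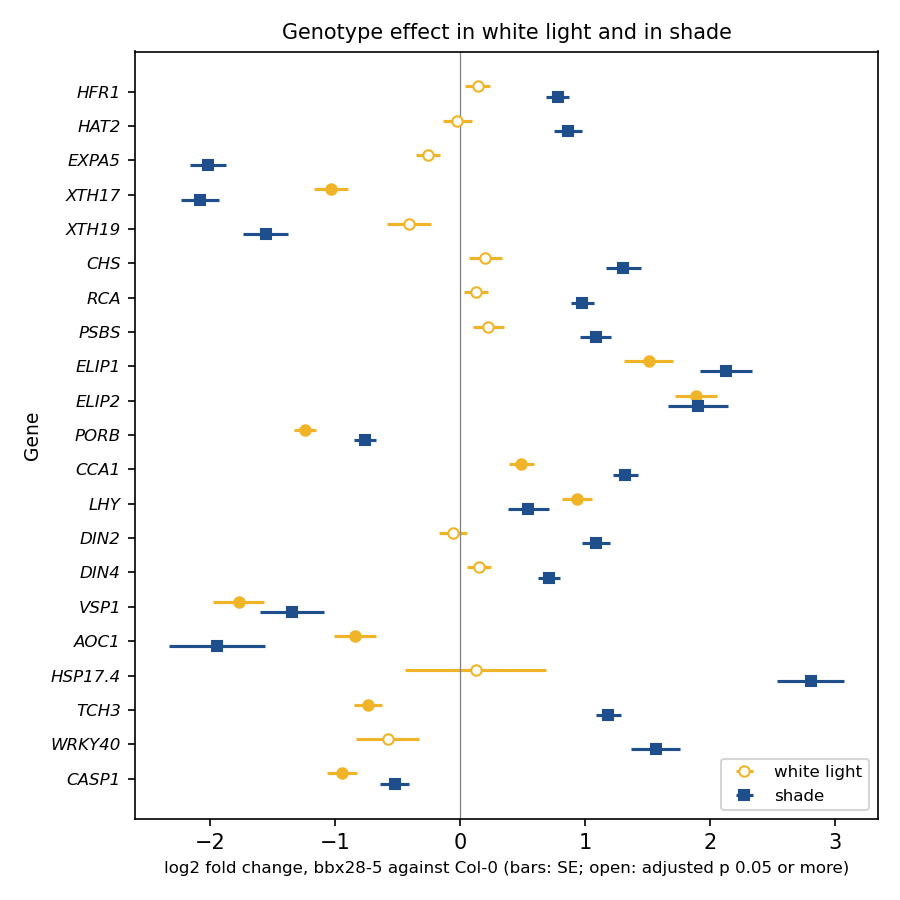
Log2 fold change of bbx28-5 against Col-0 (x axis) for 21 members of the fixed lists (y axis) in white light (circles) and shade (squares). SE bars come from the joint fit of all 12 libraries, 3 per group, and symbols are open where the adjusted p did not pass. EXPA5, XTH19 and RCA passed in shade and not in white light, with interactions of -1.76, -1.15 and 0.85, while TCH3 is at -0.74 in white light and 1.19 in shade; no direction past the threshold turned with total counts.

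In shade 6974 genes differed by genotype, 4124 higher and 2850 lower in bbx28-5, and 1600 at least 2-fold (580 higher, 1020 lower). With total counts the number was 8043, 1507 higher and 6536 lower, or 18.7% higher against 59.1%. In a fit of only the 6 libraries compared it was lower, and below the number that such a fit gave in white light. Of the 1947 genes called in white light 1227 were called in the same direction in shade, 480 higher (157 by chance) and 747 lower (173 by chance), and 64 in the opposite direction (359 by chance), with r = 0.536 across genes. That overlap was 715 and 755 without Col0_WL replicate 1 or 2, 720 and 704 without bbx28_WL replicate 2 or 3, and 2736 without bbx28_SS replicate 2. Genes with large differences in white light also differed in shade, with CSD2 at 3.83 ± 0.154, COPT2 at -3.82 ± 0.339, FRO5 at -4.09 ± 0.449, AT5G37690 at -4.14 and AT2G23540 at -3.51. Others were the chloroplast heat shock gene HSP21 (0.996 ± 0.679 to 24.5 ± 2.39 CPM, 4.57 ± 0.32) and the amino acid transporter gene UMAMIT14 (-4.04 ± 0.353).

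Of 12 seed genes 10 were higher, also over the list alone (median 5.43, and 4.83 with 4 members of few counts at their bound; adjusted p = 2.39e-06; adjusted p = 0.199 with an estimated correlation). The cruciferin gene CRU3 went from 0.387 ± 0.228 to 162 ± 143 CPM and SESA5 was 494-fold higher by counts (682 against 2, 95% interval 136 to 4090). The summed seed list was 512 ± 404 CPM against 90.5 ± 37.2 CPM in Col-0, with 965.5, 382.5 and 188.3 CPM in the bbx28-5 libraries. Of 6 heat shock genes 6 were higher (median 2.09; adjusted p = 5.47e-05; adjusted p = 0.149 with an estimated correlation), with HSP17.6II at 3.25 ± 0.309 and HSP90.1 at 1.38. Of 6 touch and wound genes 5 were higher (median 1.12; adjusted p = 3.48e-05, and adjusted p = 0.0342 with an estimated correlation), with WRKY40 at 1.57 and ZAT12 at 0.73. For the heat shock and the touch and wound genes the counts were the same adjusted over the list alone.

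Photoprotection genes were higher in 6 of 7, also over the list alone (median 0.91; adjusted p = 1.54e-05, and adjusted p = 0.0342 with an estimated correlation), ELIP1 by 2.13 ± 0.21 and ELIP2 by 1.90 ± 0.239. With total counts 6 were higher and 1 lower (median 0.59). Light-harvesting genes were higher in 14 of 23 (15 adjusted over the list alone; median 0.45; adjusted p = 0.0035; adjusted p = 0.618 with an estimated correlation), LHCA4 by 0.73 and LHCA3 by 0.59. Their mean log2 CPM was 11.77 in bbx28_SS replicate 2 against 11.27 and 11.19 in replicates 1 and 3, and without replicate 2 the median was 0.22 with 14 higher and 2 lower (adjusted p = 0.047). With total counts 3 were higher and 2 lower. Clock genes were higher in 14 and lower in 1 of 22 (adjusted p = 0.000153; adjusted p = 0.102 with an estimated correlation), BOA by 1.39 and TOC1 by 0.59. Sugar starvation genes were higher in 7 of 9 (adjusted p = 0.00124; adjusted p = 0.199 with an estimated correlation), DIN2 by 1.09 and DIN4 by 0.71. With total counts clock genes were higher in 6 and lower in 1 (median 0.25 against 0.56) and sugar starvation genes higher in 4. Chlorophyll genes had 7 higher and 1 lower of 13 (adjusted p = 0.0445; adjusted p = 0.199 with an estimated correlation), CRD1 at 0.78 and PORB at -0.76 ± 0.0869. Their median of 0.29 turned to -0.01 with total counts, with 4 higher and 2 lower. That call ended with total counts (adjusted p = 0.0907) and without Col0_WL replicate 2 (0.0511) or 3 (0.06), bbx28_WL replicate 3 (0.0508) or Col0_SS replicate 1 (0.0706) or 3 (0.0899).

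Cell wall genes were lower in 7 and higher in 3 of 15 (3 and 8 adjusted over the list alone; adjusted p = 0.00124; adjusted p = 0.102 with an estimated correlation). XTH22, a touch-induced member, was higher by 1.33 ± 0.161. With total counts 1 was higher and 10 were lower. Auxin biosynthesis and transport genes were lower in 4 of 10, also over the list alone (adjusted p = 0.0141; adjusted p = 0.405 with an estimated correlation), YUC8 at -0.74 ± 0.153 and YUC9 at -1.48, and without bbx28_SS replicate 2 the adjusted p was 0.0968. All 4 reference genes were higher (median 0.51; adjusted p = 0.0171; adjusted p = 0.149 with an estimated correlation), ACT2 by 0.59, and with total counts 1 of 4 was (median 0.20; adjusted p = 0.0804). Adjusted over the list alone clock, sugar starvation, chlorophyll and reference genes had the same counts.

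Lists that did not pass in shade were shade markers (5 higher and 2 lower of 14, adjusted p = 0.48), auxin response (4 and 2 of 20, 0.828), light signalling (5 and 1 of 20, 0.613, median -0.04 and mean 0.08), BBX (7 and 4 of 27, 0.793), brassinosteroid (4 and 1 of 11, 0.301), gibberellin (6 and 2 of 17, 0.862), flavonoid (2 and 1 of 12, 0.48), jasmonate and defence (4 and 6 of 11, 0.301), cytokinin (0 and 2 of 8, 0.194), abscisic acid (1 and 0 of 7, 0.613) and root markers (1 and 4 of 14, 0.0855). Adjusted over the list alone the counts differed for shade markers (5 higher and 3 lower), light signalling (5 and 0), flavonoid (2 and 0) and jasmonate and defence genes (4 and 7). Medians turned negative with total counts for shade markers (0.17 to -0.15), auxin response (0.09 to -0.22), BBX (0.08 to -0.22), brassinosteroid (0.04 to -0.27) and abscisic acid genes (0.14 to -0.14). With total counts the numbers higher and lower were 3 and 4 for shade markers, 0 and 5 for auxin response, 1 and 6 for light signalling, 5 and 6 for BBX, 3 and 5 for brassinosteroid, 0 and 7 for gibberellin, 1 and 7 for jasmonate and defence, 0 and 5 for cytokinin and 0 and 7 for root markers. Without bbx28_SS replicate 2 shade markers had 4 lower, light signalling 8 higher, jasmonate and defence genes 2 higher, cytokinin genes 5 lower and abscisic acid genes 3 higher, and without replicate 1 auxin response had 7 higher. Root markers passed as lower without Col0_SS replicate 2 (adjusted p = 0.0268) and cytokinin genes without bbx28_SS replicate 2 (0.0108). Within these lists the repressor gene JAZ10 was 6.18 ± 1.65 against 1.6 ± 0.296 CPM (1.94 ± 0.247), AOC1 was lower (-1.94), VSP1 was lower (-1.34), PIF4 was higher by 0.62 ± 0.0888 and BBX17 was lower (-0.96).

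The interaction asked which shade responses differ between the genotypes. TCH3 rose 1.93 ± 0.152 log2 units more in bbx28-5 (adjusted p = 3.28e-05), from 14.2 ± 1.16 to 212 ± 12.9 CPM there and from 23.7 ± 2.73 to 93.3 ± 5.09 CPM in Col-0 (SD, n = 3). HAT2 rose more by 0.89 ± 0.159 (SE, adjusted p = 0.00421), the auxin-conjugating enzyme gene GH3.3 by 1.46 ± 0.223 (0.00171) and PAR1 by 1.24 ± 0.28 (0.0138). PAR1 started lower in bbx28-5 in white light, as given above, and most of its larger rise came from that start. The expansin gene EXPA5 fell further (-1.76 ± 0.176, adjusted p = 0.000122). RCA fell less, by 0.85 ± 0.133 (adjusted p = 0.00186), as did PSBS (0.86 ± 0.174).

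In total 2032 genes passed for the interaction, 1285 with a higher and 747 with a lower log2 shade effect in bbx28-5, and 675 at least 2-fold. Among those with an average shade call, 1012 rose more and 48 rose less in bbx28-5, and 655 fell more and 156 fell less. Another 161 had no average shade call. The average includes the bbx28-5 shade libraries, so a change particular to them counts as a larger response in either direction. With total counts 3120 passed, 479 higher and 2641 lower, with 371 rising more and 178 less, and 2194 falling more and 76 less. The number was 1277 and 1227 without Col0_WL replicate 2 or 3, 1153, 1182 and 1196 without bbx28_WL replicates 1 to 3, 1350, 1303 and 1130 without Col0_SS replicates 1 to 3, and 4545 without bbx28_SS replicate 2. The largest differences included HSP21 (3.43 ± 0.692, adjusted p = 0.008), RTFL21 (2.61 ± 0.384), AT2G29500, a small heat shock protein gene (2.31 ± 0.297), and AT2G15020 (-3.38 ± 0.329).

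The shade response score, over 14580 genes, was -0.03 ± 0.018 in Col-0 and 0.00 ± 0.0085 in bbx28-5 in white light, and 0.86 ± 0.014 and 1.15 ± 0.029 in shade (SD, n = 3). The response was 0.888 ± 0.013 in Col-0 and 1.14 ± 0.018 in bbx28-5 (SE), a ratio of 1.29 and a difference of 0.255 ± 0.022. Genes and signs were taken from an average that includes the bbx28-5 shade libraries. A change or spread particular to those libraries therefore adds to the ratio and the difference. The two-sided exact permutation test over 400 arrangements gave p = 0.1. All 40 arrangements that kept the shade grouping or its mirror, and no other, gave a difference as large. White light scores differed by 0.0298 between the genotypes, the largest of any regrouping, and shade scores by 0.285. The p of 0.1 was therefore set by the regroupings of the white light libraries and not by the size of the difference, and could not have come out lower with these white light scores. The bbx28-5 shade libraries also had fewer genes with a count than the Col-0 shade libraries, 21630 ± 209 against 22250 ± 95.6, and 12.17 ± 1.5% against 10.27 ± 0.379% of counts in the top 20 genes (SD, n = 3). At similar totals of 12.51 and 12.4 M bbx28_SS replicate 3 had 21835 such genes and Col0_SS replicate 2 had 22183. Mitochondrial transcripts held 0.1136 ± 0.0226% and 0.08787 ± 0.0132% of counts, with overlapping libraries.

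**Figure D4:**
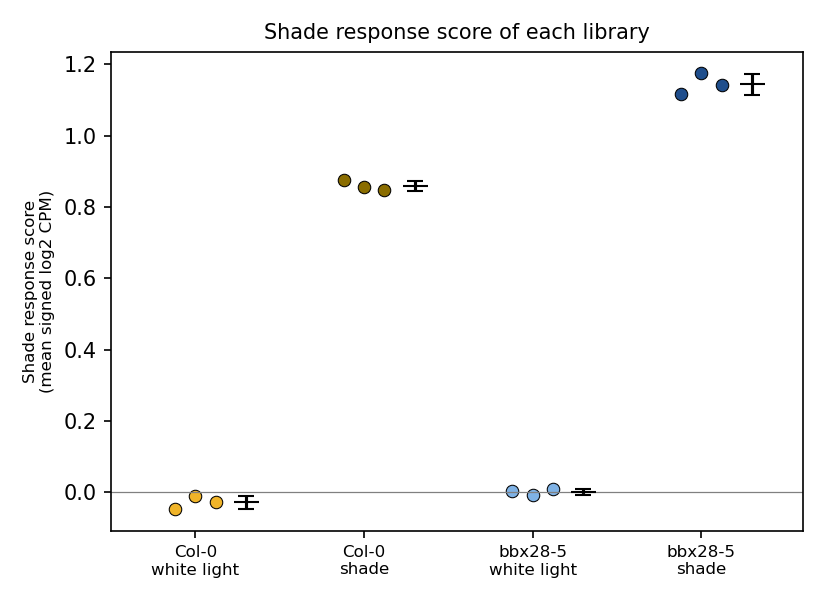
Shade response score (y axis, mean signed log2 CPM over 14580 genes) of each of the 12 libraries by group, with the mean and SD of 3 libraries beside the points. The bbx28-5 shade libraries lie at 1.116 to 1.175 and the Col-0 shade libraries at 0.8475 to 0.8748.

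Of 6 touch and wound genes 4 had a larger rise, also over the list alone (median 1.09; adjusted p = 2.36e-06, and adjusted p = 0.0134 with an estimated correlation), WRKY40 by 2.14 ± 0.317. With total counts 2 of these 6 passed (median 0.80). Of 23 light-harvesting genes 5 had a higher effect (11 adjusted over the list alone; median 0.50; adjusted p = 2.62e-05; adjusted p = 0.538 with an estimated correlation). Without bbx28_SS replicate 2 the median was 0.30 and 14 passed, without replicate 1 11 passed, and with total counts 1 did. Of 6 heat shock genes 3 had a larger rise (5 adjusted over the list alone; adjusted p = 0.000288; adjusted p = 0.266 with an estimated correlation), HSP90.1 by 1.57 ± 0.346. Without bbx28_SS replicate 2 all 6 passed. Of 14 shade markers 4 had a larger and 1 a smaller rise (5 and 1 adjusted over the list alone; median 0.52, and 0.24 with total counts; adjusted p = 0.0139; adjusted p = 0.266 with an estimated correlation). In white light the mean log2 CPM of the shade marker list was 3.051 to 3.172 in bbx28-5 libraries and 3.35 to 3.485 in Col-0 libraries. In shade it was 5.724 to 5.966 and 5.639 to 5.724. The larger rise of that list therefore came in part from a lower start in white light, and the list did not pass for genotype in shade. HFR1 rose more by 0.64 ± 0.135 (adjusted p = 0.00978), and with total counts by 0.35 (adjusted p = 0.0862). Of 13 chlorophyll genes 4 had a higher effect (5 adjusted over the list alone; median 0.25; adjusted p = 0.0482; adjusted p = 0.266 with an estimated correlation), CRD1 by 0.76 ± 0.159. This call ended with total counts (adjusted p = 0.0814, median -0.04, 1 of 13 higher), with a replicate term (0.0634) and without Col0_WL replicate 1 (0.0694) or 3 (0.0542), any of bbx28_WL replicates 1 to 3 (0.0502, 0.0648 and 0.0551) or Col0_SS replicate 1 (0.0797) or 3 (0.0698), and without bbx28_SS replicate 2 the median was 0.39 with 7 of 13 higher.

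Lists that did not pass were auxin response (3 higher and 1 lower of 20, adjusted p = 0.0701), auxin biosynthesis and transport (0 and 2 of 10, 0.0751), light signalling (2 and 0 of 20, 0.39), BBX (3 and 3 of 27, 0.739), cell wall (2 and 5 of 15, 0.0726), brassinosteroid (3 and 0 of 11, 0.0751), gibberellin (1 and 0 of 17, 0.815), flavonoid (2 and 0 of 12, 0.543), photoprotection (1 and 0 of 7, 0.0726), clock (5 and 1 of 22, 0.0771), sugar starvation (2 and 0 of 9, 0.269), jasmonate and defence (1 and 0 of 11, 0.39), cytokinin (none of 8, 0.189), abscisic acid (none of 7, 0.276), root markers (0 and 1 of 14, 0.984), seed genes (none of 12, 0.0763) and reference genes (1 and 0 of 4, 0.0701). Adjusted over the list alone the counts differed for BBX (4 higher and 4 lower), flavonoid (2 and 1), photoprotection (3 and 0), clock (8 and 1), jasmonate and defence (4 and 2), root markers (1 and 1) and reference genes (3 and 0). BBX genes had a median of -0.09 and a mean of 0.01, and the test of root markers pointed up at a median of -0.05. With total counts medians turned negative for auxin response (-0.03), brassinosteroid (-0.13), gibberellin (-0.26), flavonoid (-0.05), clock (-0.05), sugar starvation (-0.22) and jasmonate and defence genes (-0.17), and seed genes passed as higher (adjusted p = 0.00177). The numbers higher and lower with total counts were 0 and 3 for light signalling, 2 and 5 for BBX, 0 and 6 for cell wall, 0 and 1 for brassinosteroid, 0 and 2 for gibberellin, 1 and 1 for flavonoid, photoprotection and sugar starvation, 2 and 2 for clock, 1 and 2 for jasmonate and defence, 0 and 2 for cytokinin and none for reference genes. Without bbx28_SS replicate 2 cell wall (adjusted p = 0.0105) and cytokinin genes (0.00645) passed as lower, and brassinosteroid (0.0494), photoprotection (0.0176), clock (0.009), sugar starvation (0.0463) and reference genes (0.0176) as higher. Of the clock genes 12 were then higher, of light signalling and sugar starvation genes 4 each, of BBX genes 5, of photoprotection, jasmonate and defence, seed and reference genes 3 each and of root markers 2, while 3 cytokinin genes and no auxin biosynthesis and transport gene were lower. Without bbx28_SS replicate 1 jasmonate and defence and reference genes had 3 higher each. Photoprotection (adjusted p = 0.0354), seed (0.0316) and reference genes (0.036) passed as higher without bbx28_SS replicate 3. Auxin response passed as higher (adjusted p = 0.0252) and auxin biosynthesis and transport as lower (0.0211) without bbx28_SS replicate 1, and auxin response also without Col0_WL replicate 3 (0.0467) or bbx28_WL replicate 1 (0.0249). Without Col0_WL replicate 2 cell wall genes passed as lower (adjusted p = 0.0336) and photoprotection (0.0336) and seed genes (0.00122) as higher, and cell wall genes also without Col0_SS replicate 3 (0.0476). Among their members XTH17 (-1.05 ± 0.203), XTH19 (-1.15 ± 0.251) and EXPA1 (-1.37 ± 0.311) had lower shade effects in bbx28-5, and CCA1 (0.83 ± 0.14), DIN2 (1.15 ± 0.157), JAZ10 (1.89 ± 0.347) and BBX11 (1.18) higher ones.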

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

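The tests of scaling, of GC content and length offsets and of handling or warmth were chosen only after the result was seen, and the splits of the libraries were planned.

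The shade effect differed between the genotypes, by a test of the difference itself, for 2032 genes. The touch and wound list differed at an adjusted p of 2.36e-06, with 4 of 6 members rising more in bbx28-5. Light-harvesting and photosynthesis genes differed at 2.62e-05 (adjusted p = 0.538 with an estimated correlation), heat shock genes at 0.000288, shade markers at 0.0139 and chlorophyll biosynthesis genes at 0.0482 (adjusted p = 0.266 with an estimated correlation for each of these 3). Of 100 regroupings of the genotype labels within each light, drawn from 200, 6 gave as many genes with edgeR, the real one included, and the highest other gave 3137. All 6 were among the 11 that kept the real grouping of the shade libraries, and the highest with another shade grouping gave 132. A regrouping that keeps the shade libraries apart by genotype carries their genotype difference, 6974 genes, into the contrast, so high numbers are built in. The regroupings therefore cannot decide whether chance gave the number 2032, and chance is not excluded for it. For the comparisons of 3 with 3 libraries, 11716, 13308, 1947 and 6974 genes, 1 of the 10 splits, the real one, gave as many in each, the highest other gave 0, and 10 splits are too few for a share under 0.05.

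The shade response may be larger in bbx28-5: the score response was 1.14 against 0.888, and 1012 of the genes that passed rose more and 655 fell more. The score and these counts take signs from an average that includes the bbx28-5 shade libraries. A change or a larger spread particular to those libraries thus counts as a larger response in either direction. Part of the excess may therefore be built in. Scaling alone is argued against, because over TMM, RLE and total counts at least 67.6% of the interaction genes of either shade direction had the larger response in bbx28-5, where one factor per library would favour 1 direction. Scaling together with a change or spread particular to the bbx28-5 shade libraries is not argued against by these shares. GC content or transcript length bias as the whole source is argued against too, since with offsets for these the score difference was at least 0.221, against 0.255. A fast stress response to handling or warmth stays open, because the touch and wound list was higher in bbx28-5 in shade by a median of 1.12 in all 3 libraries of the group, so it cannot be told apart from the genotype. A genotype effect on the shade response also stays open, as does RNA quality, which was not tested, and the bbx28-5 shade libraries had fewer genes with a count (21630 ± 209 against 22250 ± 95.6) and a larger share of counts in the top 20 genes (12.17 ± 1.5% against 10.27 ± 0.379%).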

How the results depend on the processing

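The offsets, the total-count versions of the score, named genes, lists and BBX28 level, and the fit without the bbx28-5 libraries of the highest seed share were chosen only after the data were seen. No summary result, list or named gene turned from one called direction to the other. RLE, DESeq2, limma-voom, the other low-count filters and the replicate term kept every count of genes within 1.5 times its value. The score difference stayed between 0.221 and 0.395. At 2-fold or more 4731, 6879, 545, 1600 and 675 genes passed (shade in Col-0, shade in bbx28-5, genotype in white light, genotype in shade, interaction), as the rule is stricter. At an adjusted p under 0.01 868, 4188 and 660 passed for genotype in white light, in shade and the interaction. With only the 6 libraries compared 5093 differed by genotype in white light and 3693 in shade. The order of these 2 numbers was the reverse of that in the main fit, 1947 and 6974. The 2 main numbers therefore do not rank the sizes of the 2 genotype effects. Total counts gave 3120 for the interaction, and leaving out bbx28_WL replicate 3 and bbx28_SS replicate 1 gave 1091 in white light. The white light number also rose without bbx28_SS replicate 2, a library outside that comparison, so it depended on what the joint fit of all 12 libraries shares. Which shared step did this was not tested, nor was the cause of the other changes. Leaving out each library in turn gave 994 to 4766 for genotype in white light, 1130 to 4545 for the interaction, 704 to 2736 for the overlap of genotype effects and 4 to 12 lists for the interaction, the highest each time without bbx28_SS replicate 2. It gave 0.50 to 0.60 for BBX28 in white light, where the call was lost without Col0_WL replicate 3. With an estimated correlation 6, 3, 1, 2 and 1 lists passed in the 5 contrasts, against 13, 12, 9, 11 and 5, and fry passed 9 for the interaction. Over the 5 contrasts fry added 15 list calls and ended 3. Those ended were light harvesting for the interaction (adjusted p = 0.081 with fry) and for genotype in shade (0.0504), and light signalling for genotype in white light (0.118). Of 519 results for named genes, leaving out each of the 12 libraries ended 306 calls in all and added 81, total counts ended 42 and added 13, limma-voom 14 and 2, the replicate term 16 and 1, no filter 5 and 5 and DESeq2 2 and 11, and RLE ended 2. In simulated data edgeR and limma-voom recovered 0 of 100 interaction differences of 1.5-fold and DESeq2 9. Those data had 200 changed genes and no shade effect, whereas 2032 genes passed for the interaction here. Recovery of 1.5-fold differences in the real data was therefore not measured.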

Other observations

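The test of a chromosome segment around BBX28 was chosen only after the result was seen. The copper genes named here fall outside the rule for named genes in part. CSD2, FRO4, FRO5 and COPT2 had been seen before the copper tests were written. CCS is also named above for white light but was not set apart as seen first.

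CSD1, the cytosolic copper/zinc superoxide dismutase, was higher in bbx28-5 by 2.24 ± 0.15 log2 units in white light and 2.19 ± 0.15 in shade (SE, n = 3 per group), and CSD2 by 3.41 and 3.83. FSD1, the iron enzyme that stands in for these when copper is scarce, was lower, at 485 ± 33.8 against 1180 ± 60 CPM in white light and 966 ± 70 against 1480 ± 84.5 CPM in shade (SD), and its difference was smaller in shade (interaction 0.67, adjusted p = 0.00613). The metal transporter genes ZIP2 (-2.36 and -1.97) and YSL2 (-1.45 and -1.74), the copper chaperone gene CCH (-1.03 and -0.71) and FRO4 (-3.43 and -4.14) were lower in white light and in shade.

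A candidate explanation is higher copper status in the bbx28-5 seedlings. Of 8 further copper genes with a direction written down beforehand, 6 changed in that direction in white light. COPT1 (0.16) and COPT6 (0.14) did not pass there. In shade 6 did so, while COPT1 (0.46) and COPT6 (0.41) went the other way. CCS is among these 8 but is already named above for white light, so it adds nothing new there. The others that changed as written down in both lights were CSD1, FSD1, CCH, ZIP2 and YSL2. Reads shared by the tandem pair FRO4 and FRO5 are argued against as the source of the whole pattern, since 6 of the 8 further genes changed in the same sense in white light. With CSD2 and COPT2, which had been seen first, it was 8 of 10 outside the pair. Whether genotype, seed lot or growth medium would set such a status was not tested.

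Seed storage transcripts were higher in all 6 bbx28-5 libraries than in the highest Col-0 library, 141.7 CPM. Of the 12 list members 6 lie on chromosome 4, as BBX28 does. Among them SESA1 to SESA4 (AT4G27140 to AT4G27170), with SESA3 named above, lie close to BBX28 (AT4G27310) by locus number. A segment around BBX28 that changes only the genes inside it is argued against as the whole source, because 4 of the 6 members on other chromosomes were higher in shade too. An effect of such a segment on genes elsewhere was not tested. The library with the most seed transcripts is argued against as well, since 10 of 10 calls held without bbx28_SS replicate 1. Ungerminated seeds among the seedlings may still contribute: of a separate list of seed genes 58.3% were higher in shade (7 of 12, and 1 in white light), a share between the limits set beforehand for and against. The 1 in white light was PAP85, already named above among the largest rises, so it adds nothing new there. The median of that list, 1.58 against 5.43 for the storage list, met the limit set against, which asked for a lower share as well. A slower loss of seed transcripts in bbx28-5, a difference in germination time and a difference in seed lot were not tested.

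Of BBX28 and the 50 tested genes on each side of it 9 differed by genotype in the same direction in both lights, against 6.31 for a mean stretch, and 17.3% of stretches of that length had as many.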
